A study of Mus musculus with 6 samples.

How the data were processed

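RNA-seq libraries of LT-HSCs from 3 Dcaf8 knockout and 3 wild-type mice were analysed from a table of raw read counts per gene that the authors deposited, with 1 column per library and no pooling. Per the labels' protocols, 50 sorted cells per library went through full-length mRNA amplification, and the amplified cDNA was tagmented, amplified by PCR and sequenced on a NovaSeq instrument. Trimmomatic 0.39, HISAT2 2.2.1, Picard 2.26.1, HTSeq 1.99.2 and DESeq2 1.38.3 and the mouse build mm39 are named, without roles or settings, per the submitters' processing notes. The gene annotation release, the strand setting and the use made of Picard are not given in the sources used here. Amplified reads carry no molecular identifiers, so counts are not independent molecules, and a floor of 3 counts covers counting error only. With 50 cells, genes at a few CPM can be missed in a library by sampling of cells and transcripts. Genes that share sequence with close copies, or overlap on opposite strands, could have exchanged reads in the authors' counting.

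Groups and replicate numbers came from the submitted labels, and the design text states no pairing. The table held 55357 Ensembl gene identifiers and no summary rows, of which 52081 (94.1%) matched a symbol in a table of gene names, covering 99.87% of the counts. At least 1 count was found for 21137 identifiers. A total of 135 identifiers shared a symbol with another; there the one with the most counts kept the symbol. The order of genes around Dcaf8 came from the GENCODE annotation of GRCm38, another build than the counts, so no coordinates are given. Total counts per library were 17790290, 20881139 and 19966967 in wild-type and 22386387, 14461864 and 22154703 in knockout replicates 1 to 3.

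The main test was edgeR 4.0.16 (R 4.3.3) on the raw counts. It used the default filterByExpr (minimum count 10, minimum total 15), TMM normalization, robust dispersion estimation and a robust quasi-likelihood fit with genotype as the only term. The quasi-likelihood method was the newer one of this version (legacy off), which had been chosen as the main method; in this release the software's own default is the legacy method, which was run as an alternative. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Standard errors of log2 fold changes were derived from the F statistic. Per-library levels of single genes in the text are TMM-normalised CPM, unless they are of neutrophil, sex, surface marker or other contamination marker genes. Those, the sums of lists and the levels of single genes in the closing section are CPM of the total count. Mean levels of lists are log2 CPM with a prior count of 2. Library measures, Dcaf8 and list means were compared by two-sided exact permutation tests over the 20 assignments of 3 against 3, whose smallest p is 0.1.

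A set of 36 gene lists with 1072 entries was written from textbook knowledge before the data were examined. They cover HSC identity and ageing, blood lineages, the cell cycle, stress, metabolism, protein turnover, interferon and NF-kB responses, cell types a marrow sort could hold, sex genes and the neighbours of Dcaf8, and Dcaf8 itself is in none. Of the entries 1054 matched directly, 17 matched through a RefSeq synonym and 1 did not match. Lists with at least 3 tested members were tested with camera of limma 3.58.1 (preset correlation 0.01), and again with an estimated correlation and with fry. Some genes stand in more than 1 list.

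The genes named were fixed by a rule set in advance. It took Dcaf8, then up to 12 genes per direction with an adjusted p under 0.05, a log2 fold change of at least 1 and no overlap between groups. Gene models without an assigned name were left out. Because none passed, the 6 per direction with the smallest unadjusted p and a mean of at least 5 CPM are given as values that did not pass. Of each called list the 4 members with the smallest p are named, of other lists at most 2, and members of the sex, mitochondrial and neighbour lists as values.

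Alternatives set before the data were examined were RLE and upper-quartile factors, no filter, a strict filter (5 CPM in 3 libraries), DESeq2 1.42.0, limma-voom with sample weights and the legacy quasi-likelihood fit. The replicate number as a block with edgeR or limma-voom, removal of mitochondrially encoded and the 20 most abundant genes, each library left out in turn, and other thresholds were also set then. The limma-voom fit with a block used sample weights too. Genes detected were recounted with a minimum of 5 counts and after thinning to 14461864 counts. A term for the female library, and DESeq2 without wild-type replicate 2, wild-type replicate 3 or knockout replicate 3, were added after seeing the data. That term covers no other library, so it takes the female library out of the comparison much as leaving it out does. The fits were tested on simulated counts drawn from the real genes' means, spread and library sizes, with 200 genes changed by known folds. At the estimated spread edgeR made 10 false calls among 14392 unchanged genes, DESeq2 113 and limma-voom 0.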

Results

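Long-term haematopoietic stem cells (LT-HSCs), the self-renewing cells at the top of the blood hierarchy, were sorted from the bone marrow of young mice, 3 with a Dcaf8 knockout and 3 wild-type. The gate took lineage-negative, Sca-1-positive, c-Kit-positive cells that carried CD150 and lacked CD48. Each of the 6 libraries came from 50 cells of 1 mouse, so replicates were separate animals. Total counts ranged from 14461864 to 22386387 per library with no difference detected between genotypes (exact permutation p = 1, two-sided, n = 3 per group). Wild-type libraries contained 15940 ± 612 detected genes and knockout libraries 16792 ± 259 (SD, n = 3 per group). Every knockout library contained more detected genes than every wild-type library, with an exact permutation p of 0.1, the smallest that 3 against 3 animals can give. With counts thinned to the shallowest library the exact permutation p was 0.2 (15725 ± 642 against 16600 ± 333 genes, n = 3 per group). Wild-type replicate 3 contained the fewest detected genes, 15244. Mitochondrially encoded genes took 0.504 to 0.633% of the counts. The 100 most abundant genes took 12.1 ± 0.29% of the counts in wild-type and 11.3 ± 0.39% in knockout libraries (SD, n = 3 per group). For this share every knockout library lay below every wild-type library (exact permutation p = 0.1).

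The comparison asked how loss of Dcaf8, which encodes a substrate receptor of CUL4-DDB1 ubiquitin ligases, alters the LT-HSC transcriptome. Dcaf8 itself (ENSMUSG00000026554) was lower in all 3 knockout libraries than in any wild-type library. Its level was 262 ± 50.7 TMM-normalised CPM (counts scaled to a common library size) in wild-type and 52.6 ± 19.2 in knockout LT-HSCs (SD, n = 3 per group), so that 20.04% of the wild-type level was still counted. The wild-type libraries stood at 290.5, 293 and 204 CPM and the knockout libraries at 74.3, 38.1 and 45.2 CPM. The log2 fold change was -2.28 ± 0.28 (SE), with the smallest p of all 14592 genes tested by edgeR and an adjusted p of 0.739. DESeq2 gave an adjusted p of 1.98e-09, and over 20 alternative settings the adjusted p ranged from 1.03e-09 to 1.00, past the threshold in the 4 DESeq2 fits alone. The exact permutation p was 0.1, the smallest possible (n = 3 per group). Counts per gene do not show which exons the remaining reads came from. Dcaf8 lies on chromosome 1 between Pex19 and Pea15a, and in the GRCm38 annotation the end of Pea15a overlaps Dcaf8 on the opposite strand. The strand setting of the counting is not given in the sources used here, so reads of the overlap could not be assigned to either gene.

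**Figure D1:**
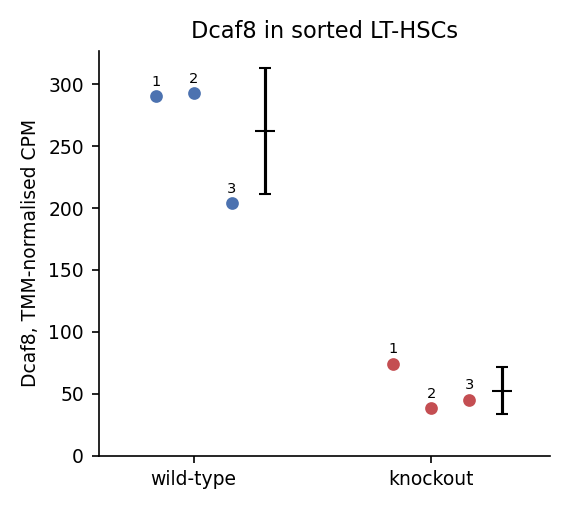
Dcaf8 in each library, in TMM-normalised CPM, for 3 wild-type (blue) and 3 knockout (red) libraries numbered by replicate; the bar beside each group is the mean ± SD. The knockout libraries sit between 38.1 and 74.3 CPM and the wild-type libraries between 204 and 293 CPM.

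Apart from Dcaf8, 12 genes are named, the 6 per direction with the smallest unadjusted p and a mean of at least 5 CPM. Malt1, the paracaspase that links antigen and growth factor receptors to NF-kB, stood at 52.6 ± 8.40 CPM in wild-type and 11.6 ± 4.98 in knockout cells, a log2 fold change of -2.28 ± 0.40 (SE, n = 3 per group). Nck2, a cytoskeletal adaptor, stood at 50.5 ± 5.59 and 15.8 ± 2.39 CPM. Tank, a TRAF-binding regulator of NF-kB and interferon signalling, stood at 112 ± 12.6 and 60.4 ± 4.02 CPM. The abundant genes Bclaf1 (log2 fold change -0.68 ± 0.13), Kif5b (-0.72 ± 0.16) and Eif5 (-0.51 ± 0.12), which encode a splicing-associated factor, a kinesin and a translation initiation factor, had values on the same side. Among genes with higher values in knockout, Ahr, the aryl hydrocarbon receptor, stood at 2.76 ± 0.599 CPM in wild-type and 17.9 ± 8.05 in knockout cells. Mmp14, a membrane-anchored matrix metalloproteinase, stood at 13.2 ± 8.04 and 75.4 ± 16.9 CPM. Serpinb6b, a serine protease inhibitor, stood at 3.36 ± 3.00 and 33.0 ± 1.18 CPM. The transcription factor genes Hivep2 and Foxj2 had log2 fold changes of 3.05 ± 0.65 and 2.85 ± 0.57, and Bbs2, a gene of the ciliary BBSome, had 4.31 ± 0.86. For each of these 12 genes every knockout library lay on one side of every wild-type library. That is no separate support, because the genes were chosen by their p in these same libraries.

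None of the 12 passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.739 for each), and DESeq2 called 10 of them, all but Serpinb6b and Bbs2. By edgeR, 0 genes were higher and 0 were lower in knockout at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 849 genes, 506 with higher and 343 with lower values in knockout, against 729.6 expected by chance. Splits of the same libraries that mixed the genotypes gave 592 to 1213 such genes by edgeR, so 849 lay within their range. limma-voom called 0 genes, with 775 at an unadjusted p under 0.05. DESeq2 called 153 genes, 100 higher and 53 lower, of which 61 had 0 counts in all libraries of 1 genotype, and it gave 1149 genes an unadjusted p under 0.05. The groups did not overlap for 10.3% of the genes tested, where chance gives 10%. The spread between libraries of 1 genotype was large, with a common coefficient of variation of 75.1%. With 1 amplified library per animal, differences between animals cannot be told apart from sampling of cells and amplification. Counts were simulated for this comparison, independently for each gene with its own estimated spread and with 50 genes changed by each fold. There edgeR called 10% of genes changed 2-fold, 40% of those changed 4-fold and 68% of those changed 16-fold, over 13856 genes tested. The simulation held no library that stands apart, and on the real counts not even Dcaf8 passed. These shares may therefore overstate what the comparison could detect.

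**Figure D2:**
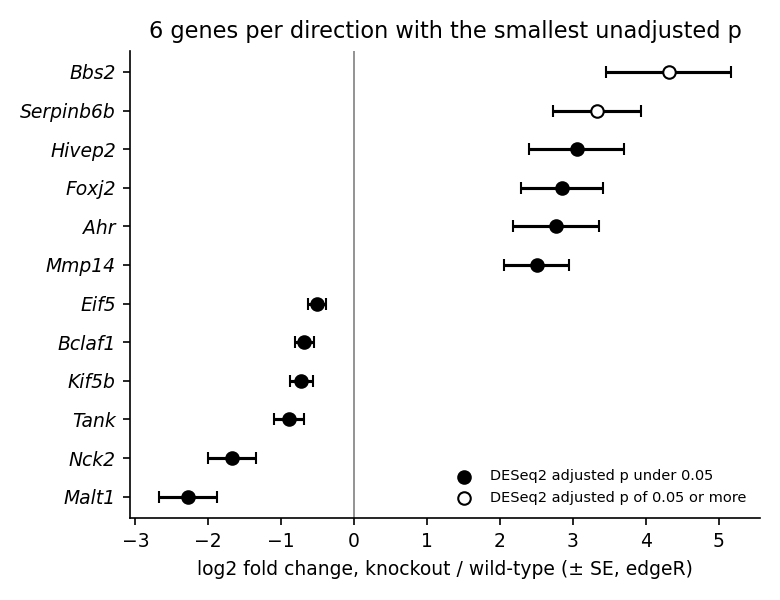
Log2 fold change (knockout over wild-type, ± SE, edgeR) of the 6 genes per direction with the smallest unadjusted p and a mean level of at least 5 CPM. Filled points had a DESeq2 adjusted p under 0.05, and 10 of the 12 genes were filled; no gene passed edgeR's adjusted threshold.

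Gene groups fixed before the data were examined were then compared with all other genes by camera, a competitive set test. At its preset correlation camera called 8 of 35 lists. With an estimated correlation 0 lists were called, and by fry 0 lists. The mixed test of fry, which asks for change in either direction, called the HSC ageing and oxidative stress lists (adjusted p = 0.0469 for each). With limma-voom and sample weights the ageing, S phase, NF-kB, immediate early and neutrophil calls ended (adjusted p from 0.0897 to 0.108). The same method, also with sample weights but with the replicate number as a block, kept these 5 (adjusted p from 8.44e-11 to 0.0409). A term for the female library, knockout replicate 3, added after seeing the data, ended the ageing, S phase, interferon, immediate early and sex gene calls (adjusted p from 0.0583 to 0.423). It takes that library out of the comparison, so it is no separate evidence beside the fit without it.

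Genes reported higher in HSCs of old mice stood higher in the young knockout cells, with 20 of 27 tested members on that side (camera adjusted p = 0.0156; adjusted p = 0.891 with an estimated correlation). The list's mean level was 4.75 ± 0.30 log2 CPM in wild-type and 5.38 ± 0.28 in knockout libraries, and its median log2 fold change was 0.26 (SD, n = 3 per group). Clu, the extracellular chaperone clusterin, stood at 49.4 ± 14.4 and 121 ± 55.7 CPM, with a log2 fold change of 1.29 that was 0.86 without knockout replicate 3. Aldh1a1, a retinaldehyde dehydrogenase, stood at 54.8 ± 14.3 and 110.0 ± 44.4 CPM. The mucin gene Muc1 was almost uncounted in wild-type, 0.0188 ± 0.0325 CPM, and stood at 5.65 ± 0.762 CPM in knockout. Ghr, the growth hormone receptor gene, lay on the other side at 28.7 ± 10.8 and 11.5 ± 4.47 CPM. No member passed over all genes or adjusted over the list alone. The call ended without wild-type replicate 1 (adjusted p = 0.320), knockout replicate 2 (0.130) or knockout replicate 3 (0.106), and over 16 alternatives the adjusted p ranged from 0.00355 to 0.320. With a term for the female library the median was 0.09 (adjusted p = 0.185).

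NF-kB targets and cytokines also stood higher in knockout (camera adjusted p = 0.0374, and 0.891 with an estimated correlation). Here the mean log2 CPM of all 3 knockout libraries lay above that of all 3 wild-type libraries (exact permutation p = 0.1, the smallest possible). Means of most lists lay higher in knockout, so a higher mean is not particular to this list. Summed CPM over the list overlapped, at 1451, 1278 and 1514 in wild-type and 2052, 1500 and 1621 in knockout replicates 1 to 3. The mean level was 4.09 ± 0.10 and 4.81 ± 0.31 log2 CPM (SD, n = 3 per group), and 14 of 23 tested members had higher values. Relb, a subunit of the noncanonical NF-kB pathway, rose from 4.07 ± 1.22 to 19.4 ± 3.97 CPM adjusted over the list alone (adjusted p = 0.0469), but did not pass over all genes (adjusted p = 0.739). It was the only member to pass adjusted over the list alone, and 0 passed over all genes. The chemokine gene Ccl3 stood at 3.46 ± 1.60 and 35.5 ± 40.1 CPM, and the Ccl3 log2 fold change of 3.47 was 1.80 without knockout replicate 1. The receptor gene Tlr2 stood at 14.4 ± 8.66 and 30.8 ± 4.03 CPM and Nfkbiz, an atypical inhibitor of NF-kB, at 102 ± 43.0 and 151 ± 10.2 CPM. The log2 fold change of Nfkbiz, 0.58, was 0.32 without wild-type replicate 2 and 0.96 without wild-type replicate 3. The list's call ended without wild-type replicate 1 (adjusted p = 0.141), wild-type replicate 2 (0.105) or knockout replicate 1 (0.306), within a range over 16 alternatives of 0.00625 to 0.306. Its median log2 fold change was 0.34, against 0.12 without knockout replicate 1 and 0.55 with no filter on low counts.

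Interferon-stimulated genes stood higher in knockout in 29 of 39 tested members (camera adjusted p = 0.0258; adjusted p = 0.981 with an estimated correlation), with mean levels of 5.28 ± 0.48 and 5.81 ± 0.24 log2 CPM that overlapped between genotypes (SD, n = 3 per group). Sp100 stood at 136 ± 10.4 and 199.8 ± 25.6 CPM and the guanylate-binding protein gene Gbp2 at 87.1 ± 22.7 and 144 ± 15.5 CPM. Oasl1 (20.3 ± 10.05 and 4.37 ± 3.90 CPM) and the GTPase gene Irgm1 (319 ± 95.7 and 201 ± 21.99 CPM) lay on the other side. The log2 fold change of Oasl1, -2.19, was -3.39 without knockout replicate 1, and that of Irgm1, -0.66, was -0.39 without wild-type replicate 3. No member passed over all genes or adjusted over the list alone. The call ended without wild-type replicate 1 (adjusted p = 0.904), wild-type replicate 2 (0.145) or knockout replicate 3 (0.618), and over 16 alternatives the adjusted p ranged from 4.08e-05 to 0.904. The median log2 fold change of 0.29 was 0.12 without wild-type replicate 1, 0.49 without wild-type replicate 3, 0.15 without knockout replicate 3 and 0.16 with a term for that female library.

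Mitotic genes stood higher in knockout in 33 of 37 tested members of the G2/M list (camera adjusted p = 1.48e-04; adjusted p = 0.981 with an estimated correlation). The wild-type libraries were far apart, at 7.04, 5.10 and 3.50 log2 CPM, and the knockout libraries stood at 6.02, 6.96 and 6.03. The lowest was wild-type replicate 3, which also contained the fewest detected genes. Cdk1, the mitotic kinase, stood at 73.2 ± 13.9 and 121 ± 20.7 CPM (SD, n = 3 per group), and its partner genes Ccnb1 and Ccnb2 at 95.9 ± 61.0 and 182 ± 62.0 CPM and at 87.5 ± 91.0 and 164 ± 43.0 CPM. Ube2c, an E2 enzyme of the anaphase-promoting complex, stood at 41.8 ± 49.7 and 105 ± 33.8 CPM. Without wild-type replicate 1 the log2 fold changes of Ccnb1, Ccnb2 and Ube2c were 1.56, 2.202 and 2.91 in place of 0.93, 0.92 and 1.34. Ccnb2 stood at 0.53 without wild-type replicate 2 and at 0.53 without wild-type replicate 3, and Ube2c at 0.82 without the latter. No member passed over all genes or adjusted over the list alone. The call ended without wild-type replicate 3 (adjusted p = 0.657), wild-type replicate 2 (0.0747) or knockout replicate 2 (0.165), and over 16 alternatives the adjusted p ranged from 6.62e-25 to 0.657. Single libraries moved the median log2 fold change both ways from 0.34, to -0.01 without wild-type replicate 3 and 0.10 without knockout replicate 2, and to 1.51 without wild-type replicate 1, 0.59 without knockout replicate 1 and 0.53 without knockout replicate 3. It was 0.95 with limma-voom and sample weights and 0.53 with a term for the female library. Genes of DNA replication and S phase stood at 6.78 ± 0.15 and 7.04 ± 0.25 log2 CPM, with 29 of 39 tested members higher (camera adjusted p = 0.0486; adjusted p = 0.981 with an estimated correlation). Ung (log2 fold change 0.76 ± 0.24, SE), E2f1 (0.73 ± 0.24), Uhrf1 (0.56 ± 0.24) and Chaf1b (0.48 ± 0.21), with roles in uracil repair, cell cycle entry, maintenance DNA methylation and chromatin assembly, had the smallest p, and no member passed over all genes or adjusted over the list alone. Uhrf1 stood at 0.36 without knockout replicate 2 and Chaf1b at 0.31 without wild-type replicate 1. Among alternatives only 5 of 16 kept the S phase call, over a range of 1.24e-05 to 0.912. It ended without wild-type replicate 1 (0.369), 2 (0.0529) or 3 (0.178) and without knockout replicate 2 (0.912) or 3 (0.403). The S phase median of 0.09 was 0.16 without wild-type replicate 2, 0.25 without knockout replicate 1 and 0.02 without knockout replicate 2.

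Immediate early genes stood lower in knockout in 16 of 27 tested members (camera adjusted p = 0.0375; adjusted p = 0.891 with an estimated correlation), although the list's mean level, 8.47 ± 0.30 and 8.37 ± 0.09 log2 CPM, overlapped between genotypes (SD, n = 3 per group). Myc stood at 703 ± 49.4 CPM in wild-type and 518 ± 26.9 in knockout cells. The Krüppel-like factor genes Klf2 and Klf6 stood at 174 ± 32.6 and 88.3 ± 29.3 CPM and at 1289 ± 193 and 995 ± 83.5 CPM, and Egr3 at 5.54 ± 5.31 and 0.462 ± 0.740 CPM. Of the knockout libraries, replicate 1 held 30 Egr3 counts and the others 1 and 0. No member passed over all genes or adjusted over the list alone. The call ended without wild-type replicate 3 (adjusted p = 0.634), without knockout replicate 2 (0.0722) and when the 20 most abundant genes and mitochondrially encoded genes were left out (0.246), within a range over 16 alternatives of 0.00595 to 0.634. The median log2 fold change of -0.09 was -0.26 without wild-type replicate 1, -0.01 without wild-type replicate 3, -0.04 without knockout replicate 1 and -0.06 without the abundant genes.

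**Figure D3:**
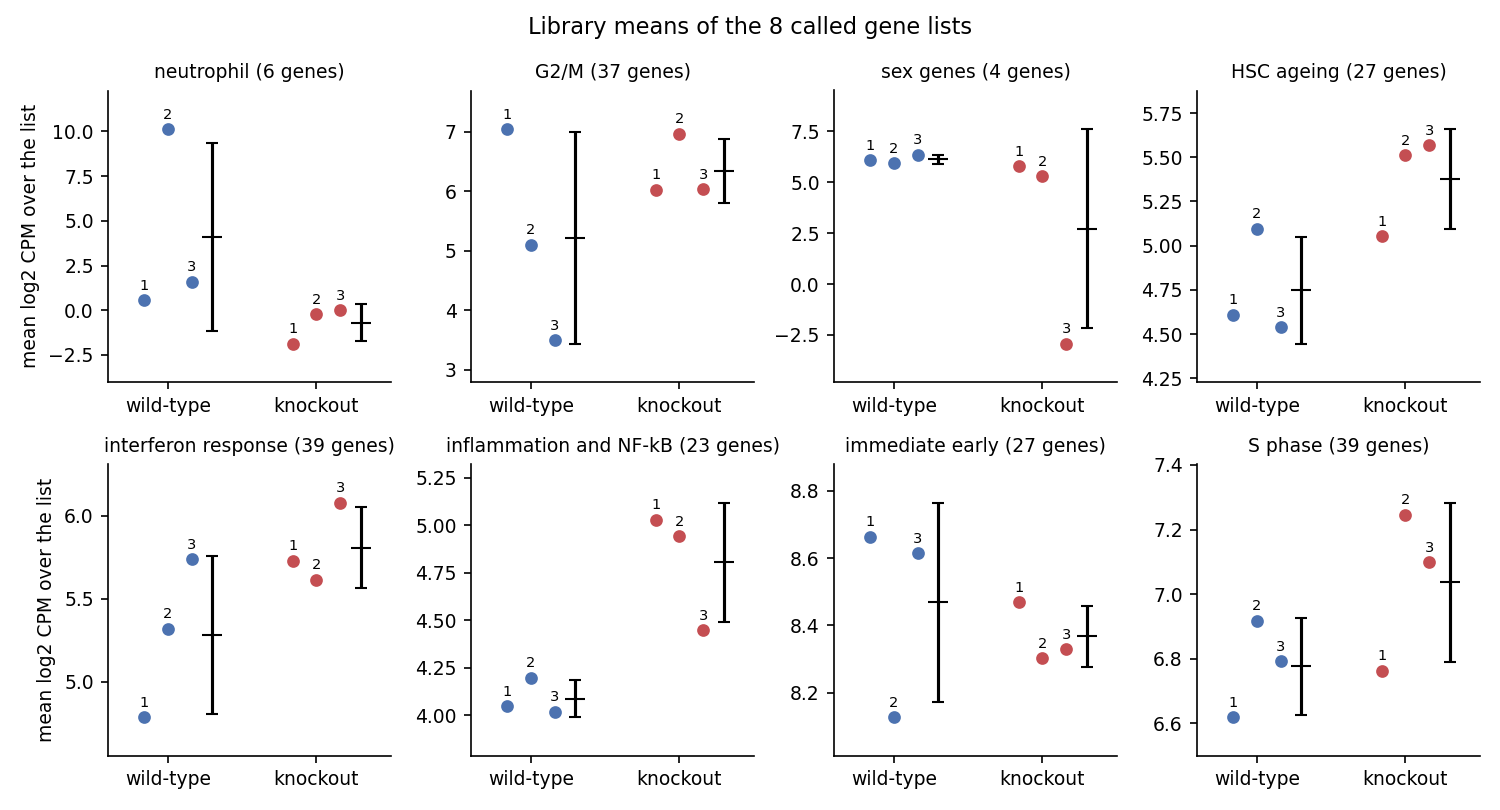
Mean log2 CPM over the tested members of the 8 called gene lists, in each of 3 wild-type (blue) and 3 knockout (red) libraries numbered by replicate, with the mean ± SD beside each group. Vertical axes differ between panels and do not start at 0. Knockout and wild-type libraries did not overlap for the NF-kB, neutrophil and sex gene lists, and overlapped for the other 5.

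In each of the remaining called lists 1 library stood apart. Neutrophil granule genes were abundant in wild-type replicate 2, where the list summed to 7800 CPM, against at most 30.7 CPM in any other library (camera adjusted p = 1.13e-04; adjusted p = 0.891 with an estimated correlation). In that library Ngp stood at 2379 CPM, Ltf at 1154, S100a8 at 875, S100a9 at 827 and Camp at 790 CPM. The macrophage and monocyte list also summed highest there, to 1001 CPM against at most 641, and its most abundant member was Lyz2, a lysozyme gene that neutrophils express too (890 TMM-normalised CPM). The haemoglobin gene Hbb-bs stood at 24.1 CPM against at most 10.8, and the B cell gene Cd79a at 4.41 CPM with 0 counts in every other library. Over the 6 libraries all 6 tested neutrophil members had lower values in knockout, and 0 of them passed over all genes or adjusted over the list alone. Without wild-type replicate 2 the list was still called (adjusted p = 0.0176), with 5 of 6 members lower. There the Ngp log2 fold change was -1.09 in place of -7.87 and the Camp log2 fold change -1.64 in place of -9.70. The S100a8 log2 fold change was -0.25 in place of -5.38, and the S100a9 log2 fold change was 0.20 in place of -6.26. The call ended with limma-voom and sample weights (adjusted p = 0.108, the highest of 16 alternatives that reached down to 3.19e-14). Y-linked genes were counted in 5 libraries and nearly absent from knockout replicate 3, where Ddx3y, Kdm5d and Uty had 0 CPM and Eif2s3y 0.181 CPM while Xist stood at 50.7 CPM. Xist was at most 1.24 CPM in every other library, so the animal of knockout replicate 3 was female and the other 5 male by these genes. The sex gene list was lower in knockout (camera adjusted p = 0.0119; adjusted p = 0.977 with an estimated correlation), with all 4 tested members on that side, 0 past either adjustment, and 8 of 16 alternatives keeping the call over a range of 0.00508 to 0.545. Its call ended without wild-type replicate 1 (0.320), 2 (0.264) or 3 (0.545) and without knockout replicate 1 (0.0780) or 3 (0.103). The median log2 fold change of -1.26 was -0.61 without knockout replicate 3, -0.61 with a term for it (adjusted p = 0.165), -3.70 with limma-voom and sample weights (call kept) and -0.74 with limma-voom and the replicate number as a block (0.373). The call also ended with no filter on low counts (0.151). In the main fit Xist was not tested, so the 4 tested members were all Y-linked. With no filter, and without wild-type replicate 1, 2 or 3 or knockout replicate 1, Xist was tested as well. There 5 members were tested, 1 of them with a higher value, so those fits tested another list than the main fit.

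**Figure D4:**
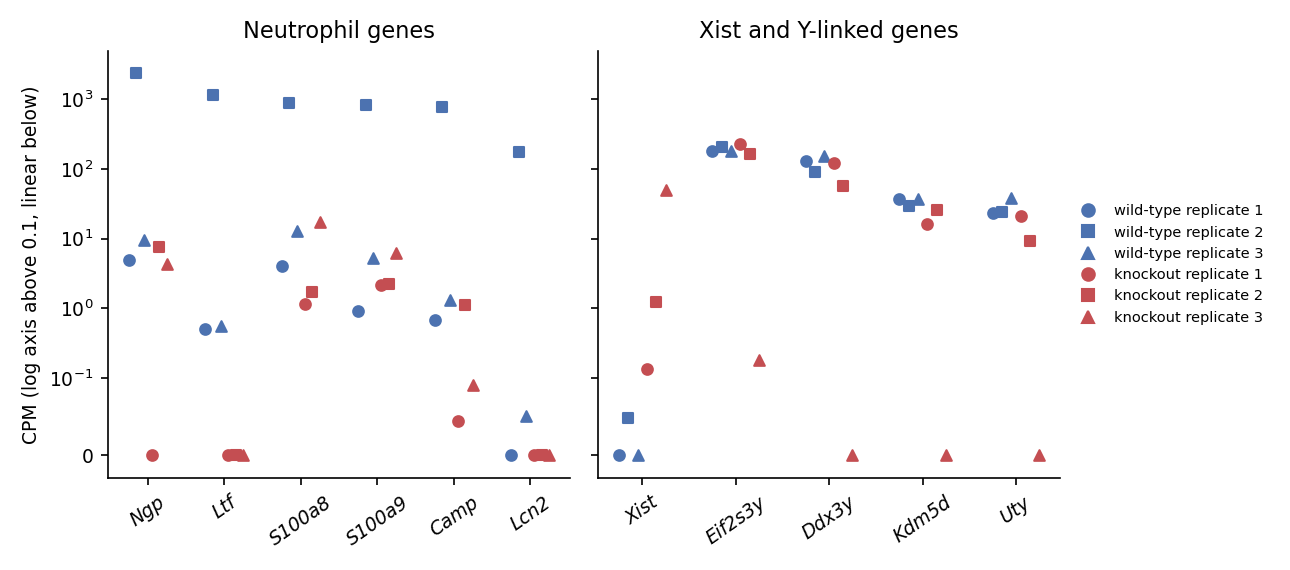
Levels, in CPM, of 6 neutrophil genes (left) and of Xist and 4 Y-linked genes (right) in each library; colour gives the genotype and the symbol the replicate, on an axis that is logarithmic above 0.1 and linear below. Wild-type replicate 2 stands apart for the neutrophil genes (Ngp at 2379 CPM), and knockout replicate 3 for Xist (50.7 CPM) and the Y-linked genes.

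The other 27 lists were not called (camera adjusted p from 0.182 to 0.987). HSC identity genes stood at 6.74 ± 0.11 log2 CPM in wild-type and 6.83 ± 0.17 in knockout libraries (exact permutation p = 0.6, n = 3 per group), with 24 of 40 members higher. Angpt1 stood at 676 ± 32.3 and 473 ± 87.4 CPM and Ctnnal1 at 88.7 ± 8.79 and 137 ± 23.0 CPM. Subunits and receptors of CUL4 ligases, without Dcaf8, stood at 5.89 ± 0.24 and 6.13 ± 0.12 log2 CPM, and the COP9 signalosome gene Cops2 at 133 ± 16.2 and 81.5 ± 2.17 CPM. Proteasome subunits had 22 of 32 members lower with a median log2 fold change of -0.04, and ribosomal proteins 60 of 78 members higher with a median of 0.06. In the oxidative stress list Nfe2l2, the gene of the transcription factor NRF2, stood at 262 ± 16.3 and 177 ± 18.4 CPM and its target Gclm at 167 ± 19.4 and 242 ± 17.8 CPM. Mean levels of MHC class II genes (4.27 ± 0.10 and 4.80 ± 0.19 log2 CPM) and of 4 stromal genes at low levels (0.06 ± 0.24 and 2.31 ± 0.32) did not overlap between genotypes (exact permutation p = 0.1 for both, n = 3 per group). Summed CPM did overlap, for the MHC class II list (401 to 573 in wild-type, 432 to 658 in knockout) and for the stromal list (7.33 to 35.5 and 20.1 to 41.3). In all, 5 of the 35 tested lists had means that did not overlap, where chance gives 10%. Means of most lists lay higher in knockout. These included lists that camera pointed down, such as quiescence (5.79 and 5.88 log2 CPM) and p53 targets (4.03 and 4.13). Others lay lower, such as proteasome subunits (7.915 and 7.865).

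Lineage programmes without a call were the megakaryocyte, myeloid progenitor, erythroid and lymphoid-primed lists. For myeloid progenitor genes the test pointed up while the median (-0.12) and mean (-0.42) log2 fold changes were negative, and Prtn3, a neutrophil serine protease gene, stood at 139 ± 23.6 and 240.5 ± 37.3 CPM (SD, n = 3 per group). For megakaryocyte genes the test and the median (-0.07) pointed down and the mean (0.05) up. The lists of quiescence, p53 targets, DNA repair, DNA methylation and the reported DCAF8 substrate LSH, apoptosis, oxidative phosphorylation, glycolysis and hypoxia, unfolded protein response, autophagy and lysosome, adhesion and homing, and mitochondrially encoded genes were not called either. Nor were the contamination lists of T and NK cells, macrophages and monocytes (highest in wild-type replicate 2), endothelial cells, and basophils and mast cells. The mature B cell list had 2 tested members and was not tested. Genes around Dcaf8 formed an uncalled list of 57 members, of which 38 were tested. Its adjacent genes Pex19 and Pea15a had log2 fold changes of -0.04 ± 0.25 and 0.18 ± 0.30 (SE). Slamf1, the gene of the sort marker CD150, stood at 140 ± 31.9 and 117 ± 12.9 CPM. Cd48, the gene of the marker the gate excluded, stood at 6.36 ± 5.90 and 20.3 ± 12.7 CPM, with its highest level, 34.4 CPM, in knockout replicate 2. Kit stood at 411 ± 155 and 450 ± 137 CPM, and Ly6a, the gene of Sca-1, at 145 ± 19.5 and 203 ± 21.4 CPM (SD, n = 3 per group).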

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

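The term for the female library and the DESeq2 fits that leave out a library were chosen after seeing the data. By edgeR and limma-voom, 0 genes were higher and 0 lower in knockout under every alternative run, each library left out in turn included, with 559 to 1445 genes at an unadjusted p under 0.05. DESeq2 called 100 higher and 53 lower. Without wild-type replicate 2 it called 334 and 82, without wild-type replicate 3 316 and 83, and without knockout replicate 3 72 and 212. Of its 153 calls on 6 libraries, 110, 102 and 66 remained; the cause was not tested. The Dcaf8 log2 fold change lay between -2.64 and -2.13 over 20 alternatives. It passed the threshold only in the DESeq2 fits, at -2.32 with 6 libraries, -2.24 without wild-type replicate 2, -2.47 without wild-type replicate 3 and -2.22 without knockout replicate 3; the cause was not tested. The number of called lists, 8, was 0 with an estimated correlation, 0 with fry and 3 with limma-voom and sample weights. It was 5 with the term for the female library and 3 to 6 with a library left out. The term and the left-out fits both compare fewer libraries, and beyond that the cause was not tested. Other settings gave 6 to 9. Of 128 alternative values of the 8 called lists, 87 kept the call, 41 lost it and 0 turned camera's direction, although 1 median turned sign (G2/M without wild-type replicate 3, -0.01). Single-gene alternatives covered Dcaf8, the 12 genes with the smallest unadjusted p, and the 4 members named from each called list except the sex genes. Other genes given as values were not rerun. A left-out library moved the log2 fold change of 15 of the genes covered by over 1.5 times. Of 790 alternative values of the 40 covered besides Dcaf8, 60 passed the threshold, all in DESeq2 fits. Of these 790, 2 reversed: without wild-type replicate 2 the S100a9 log2 fold change was 0.20 by edgeR, the highest value with a library left out (the lowest was -7.03), and 0.17 by DESeq2, since that library held nearly all its counts. Normalization moved the median log2 fold change of all genes by under 0.1 (0.009 with TMM, -0.003 with upper-quartile factors).

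Deviations of same-numbered libraries from their group means had correlations of 0.059, -0.038 and 0.006 across genes. Replicate 1 correlated best with its own number (0.059 against -0.011), and replicates 2 and 3 did not (-0.038 against 0.038 and 0.006 against 0.042). Values this near 0 cannot decide whether the numbers pair the animals, and the design text states no pairing. With a replicate block edgeR called 0 genes higher and 0 lower, the Dcaf8 log2 fold change stood at -2.29, and 9 lists were called; with a replicate block and limma-voom these were 0, 0, -2.32 and 8. The knockout libraries' excess of 852 detected genes was 834 with a minimum of 5 counts (exact permutation p = 0.1, n = 3 per group). It was 876 after thinning to equal depth (exact permutation p = 0.2). Genes at a few CPM rest on few counts from 50 cells, which limits what their values show.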

Other observations

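The tests of splits for counts of genes, those on the neutrophil genes, on the overlap of G2/M levels and their order beside S phase levels, and on the ageing list without wild-type replicate 3 were chosen only after the result was seen. Some genes were counted in every library of 1 genotype and in none of the other, and these, like the other genes named in this paragraph and the next, were chosen after their values were seen. A level of at least 1 CPM in all 3 knockout libraries with 0 counts in all 3 wild-type libraries was found for 34 genes, and the opposite for 4. Every knockout library also contained more detected genes (16508 to 17015) than every wild-type library (15244 to 16393). Thinned to equal depth, the mean excess was 876 genes in place of 852. The ranges then overlapped only between 16223 and 16249 (16223 to 16854 against 15009 to 16249, exact permutation p = 0.2, n = 3 per group). The 4 were B3galnt1, a glycosyltransferase gene, Pacsin3, which encodes an endocytic adaptor, and the gene models Gm28791 and Gm38380. B3galnt1 stood at 9.94 ± 5.78 CPM in wild-type (SD, n = 3) and was at least 62.5-fold lower in knockout, taking a floor of 3 counts per library. Among the 34, the zinc finger gene Zfp78 stood at 12.9 ± 5.83 CPM in knockout (at least 83.8-fold higher, with the same floor), the integrin gene Itgb6 at 9.33 ± 6.58 CPM and the immune adaptor gene Clnk at 8.66 ± 1.07 CPM. With only 10 splits of the 6 libraries, a share under 0.05 cannot be reached; the real split gave 38 such genes and the highest other split 42, with 2 of 10 splits giving as many as the real one.

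Among the 153 DESeq2 calls, 42 had a mean of at least 50 CPM, 15 higher and 27 lower in knockout. Irf1, an interferon-responsive transcription factor gene, stood at 262 ± 32.7 CPM in wild-type and 119 ± 49.5 in knockout (DESeq2 adjusted p = 0.0310). H3f3b, a gene of histone H3.3, stood at 4505 ± 214 and 3620 ± 366 CPM (0.0453), and Rictor, a core gene of mTORC2, at 90.6 ± 12.5 and 53.4 ± 4.38 CPM (0.0121). Myc and Nfe2l2 were also among these calls (0.00222 and 0.00874). None of the 5 passed by edgeR. The splits are again too few for a share under 0.05. The real split gave 153 DESeq2 calls and the highest other split 312, with 3 of 10 splits giving as many as the real one. That highest split set wild-type replicate 1 and knockout replicates 1 and 2 against the rest. For edgeR the real split gave 0 calls and the highest other split 0, so all 10 splits gave as many. For the lists called by camera the real split gave 8 and the highest other split 10, with 2 of 10 splits giving as many.

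The neutrophil genes of wild-type replicate 2 may come from neutrophils or their RNA in that sort, although the lineage gate would remove such cells. Each of the 6 tested genes stood at least 50.4 times above the highest of the other 5 libraries. Granulocyte progenitors stay open. Of the primary granule genes Mpo, Elane, Prtn3, Ctsg and Ms4a3, Ctsg was counted in no library and Elane not in this one, and the median ratio of 0.887 to the highest other library over the remaining 3 decides nothing, as Prtn3 was high in all 6 libraries. A difference between genotypes at low levels stays open and was not tested further. Camera still called the list without wild-type replicate 2 (adjusted p = 0.0176, against 0.891 for all 6 libraries with an estimated correlation), with 5 of 6 members lower. Its mean level in wild-type replicates 1 and 3, 0.56 and 1.59 log2 CPM, lay above that of all knockout libraries (-1.86, -0.21 and -0.0021). That mean rests partly on genes near 0, as 2 of the 6 tested members had 0 counts in all knockout libraries. Summed over the list, wild-type replicates 1 and 3 (12.0 and 30.7 CPM) overlapped knockout replicates 1 to 3 (3.39, 21.6 and 28.1 CPM).

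The G2/M list was called higher in knockout, but not with an estimated correlation (adjusted p = 0.981) nor without wild-type replicate 3 (median log2 fold change -0.01, adjusted p = 0.657, in a range of 6.62e-25 to 0.657 over 16 alternatives). A general loss of detection in wild-type replicate 3 is argued against as the whole cause of its low level, since the list's median deviation there, -1.92 log2 units, lay at percentile 0 of 10000 random lists matched on expression, 95% of which lay between -0.19 and 0.22. A share of cycling cells that varies from library to library within a genotype stays open, as library levels overlapped (exact permutation p = 0.5, n = 3 per group). S phase levels ranked as G2/M levels did among the knockout libraries (7.25, 7.10 and 6.76 against 6.96, 6.03 and 6.02 log2 CPM in replicates 2, 3 and 1) and in wild-type replicates 2 and 3 (6.92 and 6.79 against 5.10 and 3.50), but wild-type replicate 1 had the highest G2/M level (7.04) and the lowest S phase level (6.62). An effect of genotype on cycling stays open too.

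The HSC ageing list was called higher in knockout, but not with an estimated correlation (adjusted p = 0.891). A general shift of genes at that expression level is argued against, with the median log2 fold change of 0.26 at percentile 99.55 of matched random lists (95% between -0.15 and 0.18). Lower detection in wild-type replicate 3 is argued against too, as camera still called the list without that library (adjusted p = 0.0232, in a range of 0.00355 to 0.320 over 16 alternatives). A contribution of the female library, knockout replicate 3, could not be put aside, since in male libraries the median was 0.20, at percentile 97.4 and thus just short of the bound set in advance, whereas the median difference of mean log2 CPM, a measure computed first and not the one set in advance, was 0.39 at percentile 99.87. With a term for that library the median was 0.09 over 27 tested members, against 32 in male libraries alone, and an effect of genotype stays open as a hypothesis, as does chance.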
